A study of Oniscidea with 6 samples.

How the data were processed

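Poly(A) RNA from fresh woodlouse tissue (Oniscidea, the terrestrial isopod crustaceans) was sequenced on an Illumina protocol in 6 samples, 3 labelled rolling and 3 labelled stretching. The labels state that no treatment was given. They give only the suborder, and they do not say whether the groups were of one species, sex or stage, which tissue was taken, or whether the samples of a group came from separate animals.

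The deposited table holds 1 signal value per gene and sample, which is the number of reads on a gene divided by one size factor per sample. It names 24421 features by mouse gene symbols. BWA, DESeq2 and the mouse build mm10 are named in the submitters' processing notes, without versions, roles or parameters, and the counting program and annotation are not given in the sources used here. Whether reads were aligned to mouse sequence directly, or assembled transcripts were given mouse names, is not stated. A gene symbol is therefore only the mouse name under which reads were counted. It does not name a woodlouse gene, and how the reads were matched to mouse sequence across so wide an evolutionary distance is not given in the sources used here. The labels also name a separate assembly of transcripts for each group, which was not used here. The authors' deposited table further gives, per its file headers, a mean signal, a log2 fold change with its standard error, a p-value and an adjusted p-value for each feature, in the form that DESeq2 writes.

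The columns are headed with the words curl and strait and a number from 1 to 3. They were taken as rolling and stretching by the meaning of these words, with the number as the replicate. The sign of the authors' deposited log2 fold change follows the curl columns over the strait columns. No column of sample values was left unused.

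Whole reads were recovered by dividing each column by its smallest value above 0, and the largest deviation from a whole number was 1.0e-09. With DESeq2 1.42.0 run on these reads, the size factors differed from the authors' by 0, the log2 fold changes differed by at most 4.1e-05, and 3951 features were called, all 3951 of them also called in the authors' deposited table. Counted reads per library were 539367, 416821 and 1122154 in rolling samples 1 to 3 and 456331, 403971 and 544157 in stretching samples 1 to 3. Reads that were not counted on a listed feature are not included, and their number is not known. All shares of reads given here are shares of the counted reads. Between 40.1% and 79.5% of the reads of a library lay on the 20 features with the highest mean. At this depth, a feature with a mean of 10 rests on few reads, and 3 reads in a library correspond to a normalised value between 1.58 and 3.67. Counting intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

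The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(value + 1), for the 2948 features with a mean value of at least 10 over the 6 samples. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are rolling minus stretching on the log2(value + 1) scale, which understates the change of low features, and the fitted change of a feature with few or no reads in a group depends on the pseudocount. For a feature without reads in a group, the fold was computed against a floor of 3 reads over the group and is a lower bound. For a feature with 1 to 3 reads in a group, the ratio of reads adjusted for depth is given with its 95% counting interval. Sums over genes were compared with an exact two-sided permutation test, for which the smallest p that 3 samples against 3 can give is 0.1.

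Gene lists, the named genes, the test and the alternatives were fixed before the data were examined, except where stated. The 24 lists covered Hox genes, other homeobox and segmentation genes, markers of muscle, neurons, gut, haemocytes, cuticle and vertebrate tissues, calcium handling, chaperones, energy metabolism, translation, histones, the cytoskeleton, cilia, the proteasome, ion transport, the cell cycle, splicing, signalling pathways and abundant noncoding RNA. They were matched by mouse symbol without regard to case. Lists with at least 5 tested members were tested with camera of limma, with its preset correlation and again with an estimated one, and with fry. The genes named are the 12 with the largest positive and the 12 with the largest negative fold change among called features with a mean of at least 100 and no overlap between groups, leaving out gene models without a functional name. All measured Hox genes, the 3 tested members of each list with the highest mean, up to 2 called members of each list with the smallest adjusted p, and the 5 features with the highest mean were also eligible. Not all of these are discussed, and some are not reported here.

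The alternatives were pseudocounts of 0.5 and 8, no filter, a minimum mean of 100, TMM scaling, quantile normalization, scaling to library totals, leaving out the 20 most abundant features, no trend, a minimum 2-fold change, edgeR 4.0.16 and DESeq2 on the recovered reads, the authors' deposited adjusted p, the replicate number as a block, and leaving out each sample in turn. After the data were examined, a fit without rolling 3 and stretching 3 and an edgeR fit with the authors' size factors were added. Pairs of samples within a group differed by far more than sampling noise, with a chi-square per degree of freedom between 19.6 and 199, so all 6 were kept as separate samples.

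The test was run first on simulated counts for the 2948 features with seeded changes. There limma found 4.48% of the 67 features changed 2-fold, 47.8% of the 67 changed 4-fold and 100% of the 66 changed 16-fold. It made 5 false calls, or 4.72% of its calls. The other simulated features were unchanged and were scaled with known size factors, whereas 75.2% of tested genes were called in the data. These rates therefore need not carry over, and an error of scaling was not simulated. Against this background camera found the seeded list and called 0 of 20 unchanged lists. Its power where most genes differ was not checked. The test of gene family totals was checked on 100 shuffles of the gene names, of which 2 gave a share under 0.05. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Coordinates, gene lengths and base composition were not analysed here.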

Results

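Woodlice are terrestrial crustaceans, some of which roll into a ball when disturbed. RNA of 3 rolling and 3 stretching samples was compared to ask which genes differ between these states, with Hox genes, the transcription factors that set segment identity along the body axis, named in the title of the series. Each gene named here is a mouse symbol under which reads were counted, and not a known woodlouse orthologue. Reads counted under mouse symbols numbered 416821 to 1122154 per library in the rolling group and 403971 to 544157 in the stretching group. The number of reads not counted is not known. Of 24421 mouse genes, 18260 had a read in any library and 4010 had reads in all 6. The 2948 genes with a mean normalised read count of at least 10 were tested, and they held 87.6% to 97.3% of the reads of each library. Nothing in the labels says that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

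Csn2, the mouse gene of the milk protein beta-casein, had a normalised read count of 6248 ± 2238 in rolling samples (SD, n = 3) and no read in stretching samples, which makes it at least 6365-fold higher in rolling. Poc5, a centriole protein, stood at 17618 ± 11296 in rolling and rested on 50562 reads there against 1 in stretching, a ratio of 39366 with a 95% counting interval of 7065 to 1554910. In the other direction, Olfm1, a secreted olfactomedin, stood at 5064 ± 572 in stretching samples (SD, n = 3), had no read in rolling samples and was at least 6178-fold lower there. The fitted log2 fold change of Poc5 was 13.44, and 14.23 without rolling 1. Foxo6, a forkhead transcription factor, rested on 23832 reads in stretching against 1 in rolling, a ratio of 30610 with a 95% counting interval of 5493 to 1209080. Of the 2948 tested genes, 2217 (75.2%) differed between the groups by limma with Benjamini-Hochberg adjustment, 1114 higher and 1103 lower in rolling.

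Among the other genes with the largest increase in rolling were Zfp444, a zinc finger protein, at least 2570-fold higher, the deubiquitinase Otub2, at least 1830-fold higher, and the RNA-modifying enzyme Tut1, at least 1182-fold higher. Igf1, insulin-like growth factor 1, rose from 6.67 ± 8.94 to 5700 ± 1651 (SD, n = 3), with a log2 fold change of 10.17 (SE 0.74). Most of its stretching signal lay in stretching 2, and the log2 fold change was 11.12 without that library and 9.57 without stretching 3. Wdr47, Mettl5, Ivl and Pop1 had 1 or 2 reads in the stretching group and between 5084 and 13181 in the rolling group. Their ratios, each with its 95% counting interval, were 10262 (1842 to 405372), 2907 (804 to 24007), 3133 (867 to 25878) and 3958 (710.1 to 156373). The fitted log2 fold change of Ivl was 10.51, and 11.18 and 9.85 without rolling 1 and 3. Fbxo17 and Ccdc90b rose by 10.50 and 10.02 on the log2 scale. Fbxo17 stood at 11.64 without rolling 1 and 9.48 without rolling 3, and Ccdc90b at 10.72 without rolling 1, 10.69 without stretching 1 and 9.42 without stretching 2. Among the genes with the largest decrease was Nags, N-acetylglutamate synthase, at least 932-fold lower in rolling, with a fitted log2 fold change of -9.25 that became -9.96 without stretching 2. Polg, the mitochondrial DNA polymerase, had 2 reads in rolling against 10012 in stretching (ratio 6430, 1779 to 53100), and Clstn1, Lta4h, Ggt5 and Ppef2 had 1 to 3 reads in rolling against 2222 to 8712. Their ratios were 3730 (1276 to 18090), 5260 (943 to 207794), 4822 (865 to 190495) and 2854 (512 to 112775). Timd2 and Jakmip2 had log2 fold changes of -12.14 and -9.28, with 6 reads each in rolling.

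**Figure D1:**
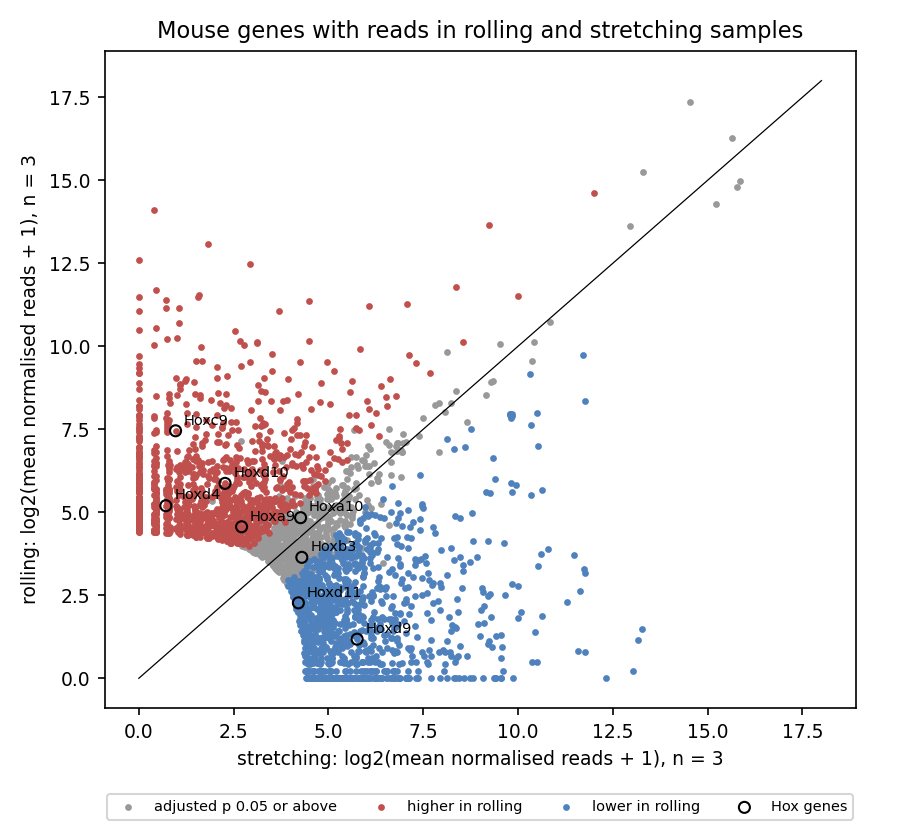
Mean normalised read count plus 1 on a log2 scale of each of the 2948 tested genes in stretching (x axis) and rolling samples (y axis), n = 3 each, with genes coloured by the limma call and Hox genes circled. The 1114 genes higher and 1103 genes lower in rolling spread out along both axes, and genes on an axis had no read in the other group.

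The median absolute log2 fold change of the called genes was 3.70, and 973 of them (43.9%) exceeded 16-fold on this scale. A count of 720 tested genes (24.4%) had at least 30 reads in one group and at most 3 in the other, 375 of them with reads in rolling and 345 in stretching. The values of the groups did not overlap for 2319 genes (78.7%), where chance gives 10%. The median log2 fold change of all tested genes was 0.10. The size factors of DESeq2 bring the median ratio between samples near 1, so this value and the even split of calls follow partly from the scaling. After scaling, the summed values of a library ranged from 284281 in rolling 1 to 1219550 in rolling 3. Principal component 1 held 91.4% of the variance and separated the groups. Pearson correlations of log2 values across the tested genes were 0.900 to 0.932 within groups and -0.342 to -0.308 between them, with genes not being independent replicates. The filter on the mean over both groups lowers the latter, since it leaves out genes that are low in both.

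Of 39 Hox genes in the table, 37 had reads and 8 reached the level for testing, of which 4 rose and 2 fell in rolling. Hoxc9 stood at 174 ± 37.6 in rolling and 0.958 ± 1.66 in stretching (SD, n = 3), with a log2 fold change of 6.78 (SE 0.57; limma adjusted p 6.2e-06). It rested on 677 reads against 3, a ratio of 176 with a 95% counting interval of 59.9 to 854. Hoxd4 rose by 4.61 (SE 0.55), with 138 reads against 2 and a ratio of 53.7 (14.6 to 448), and Hoxd10 rose by 3.57 (SE 0.40), from 3.84 ± 0.827 to 57.5 ± 17.5. Hoxd9 went the other way, from 53.1 ± 1.30 in stretching to 1.26 ± 1.75 in rolling, a log2 fold change of -4.86 (SE 0.55; limma adjusted p 4.1e-05). Without stretching 1 the value of Hoxc9 was 7.43, and without rolling 3 that of Hoxd9 was -5.45.

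Hoxd11 fell by 2.01 on the log2 scale (SE 0.44; limma adjusted p 0.0026), from 17.5 ± 2.70 to 3.83 ± 2.07. Hoxa9 rose by 2.12 (SE 0.62; limma adjusted p 0.011), with an adjusted p of 0.051 without rolling 1 and a log2 fold change of 1.40 without stretching 1. Hoxa10, with 27.6 ± 21.6 in rolling and 18.2 ± 13.3 in stretching, and Hoxb3, with 11.5 ± 6.20 and 18.7 ± 12.3, did not differ by more than the spread between replicates. The number of called Hox genes was 6 over all genes tested and 6 when adjusted over the list alone.

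The other 29 Hox genes with reads had a mean under 10 and were not tested here. Hoxb9 had 0 reads in rolling and 45 in stretching, Hoxc12 had 0 and 24, Hoxd12 had 0 and 25, and Hoxc13 had 44 and 1, a ratio of 34.3 (95% counting interval 5.84 to 1383). These 4 were called in the authors' deposited table, which called 10 Hox genes, 5 higher and 5 lower in rolling, and gave no adjusted p for 16. All Hox genes together held 147 to 788 reads per library, or 0.0340% to 0.146% of the reads. Summed, they stood at 404 ± 30.3 in rolling and 187 ± 19.5 in stretching (SD, n = 3), a log2 fold change of 1.11 (SE 0.11; exact permutation p 0.1, the smallest this design allows).

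**Figure D2:**
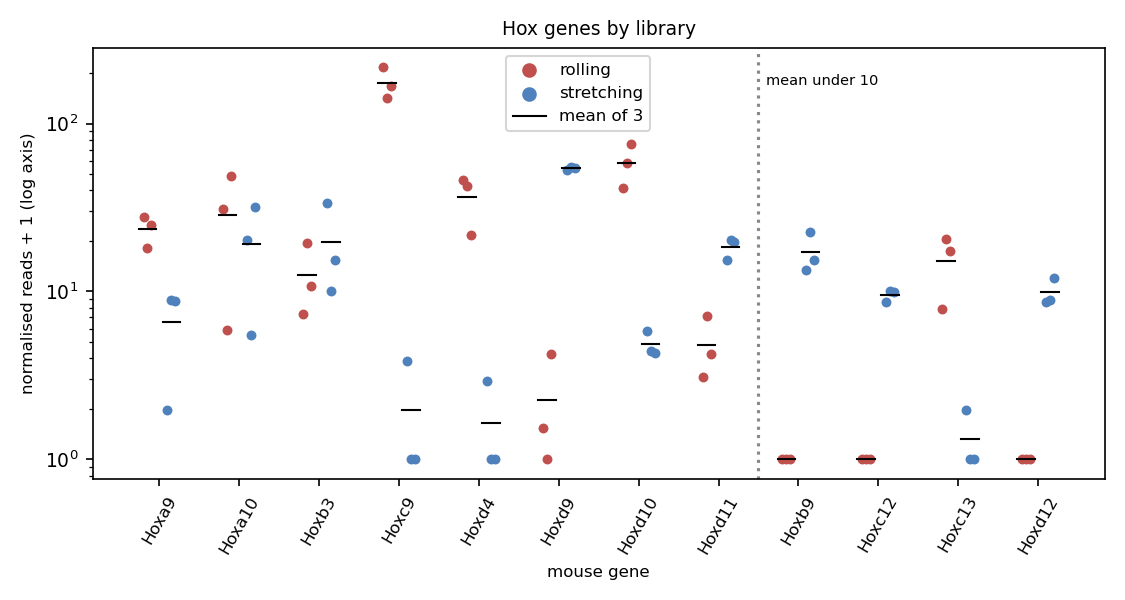
Normalised read count plus 1 (log axis) of the 8 tested Hox genes and, right of the dotted line, of 4 Hox genes with a mean under 10, with 1 point per library and a bar at the mean of 3. Hoxa9, Hoxc9, Hoxd4 and Hoxd10 lay higher in rolling and Hoxd9 and Hoxd11 in stretching.

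Of 6 tested genes among the other homeobox and segmentation genes, 3 rose and 2 fell. Pax3, a paired-box transcription factor, stood at 27.4 ± 3.14 in rolling with 102 reads against 2 (ratio 39.7, 95% counting interval 10.7 to 332), and Nkx2-2 had 114 reads against 3 (ratio 29.6, 9.87 to 146), with a fitted log2 fold change of 3.96 and of 4.68 without stretching 2. Nkx2-1 fell by 1.13 on the log2 scale (SE 0.36; limma adjusted p 0.016), and its adjusted p was 0.053 without stretching 3, 0.113 with scaling to library totals and 0.078 in the authors' deposited table.

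Genes of calcium handling and excitation rose in 9 and fell in 3 of 21 tested cases. Atp2a1 and Atp2a2 both encode calcium pumps of the sarcoplasmic reticulum. Atp2a1 rose from 2.13 ± 0.188 to 1013 ± 552 (SD, n = 3), a log2 fold change of 8.21 (SE 0.42), and Atp2a2 fell from 666 ± 259 to 62.6 ± 25.2, a log2 fold change of -3.39 (SE 0.46). Camk2d, a calmodulin-dependent kinase, rose by 3.70 (SE 0.40). Of 9 tested muscle sarcomere genes, 3 rose and 1 fell, with 3 called when adjusted over the list alone. The myosin heavy chain Myh3 rose from 158 ± 28.9 to 721 ± 218, while Myh6 fell from 1467 ± 1484 to 9.33 ± 5.18. Myh6 stood at 3081, 163 and 1158 in stretching 1, 2 and 3, and its log2 fold change of -6.47 was -5.53 without stretching 1 and -7.65 without stretching 2. The skeletal actin Acta1 rose by 2.48 (SE 0.72; limma adjusted p 0.011), and its adjusted p was 0.073 without stretching 1, 0.060 without stretching 3 and 0.057 without rolling 3 and stretching 3. Acta2 stood at 38664 ± 18948 and 9959 ± 1818 and did not pass the threshold (limma adjusted p 0.064), although it did under 10 of the alternatives, with adjusted p 0.00022 by DESeq2.

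All 4 tested neuron and synapse genes were higher in rolling, a list too short to be tested as a set. Unc13a, which primes synaptic vesicles, rose from 2.17 ± 2.96 to 760 ± 338 (SD, n = 3), a log2 fold change of 8.25 (SE 0.66). The glutamate receptor subunit Gria2 rose by 2.81 (SE 0.64), the GABA receptor subunit Gabrb2 by 2.46 (SE 0.51) and the tubulin Tubb3 by 1.71 (SE 0.43). Unc13a stood at 7.64 without stretching 2 and 9.0 without stretching 3, and Gria2 at 2.15 without stretching 1. The adjusted p of Tubb3 was 0.053 with scaling to library totals and 0.057 without rolling 3 and stretching 3. The 4 genes were also called when adjusted over the list alone, but 39 of the 43 list members with reads were under the level for testing.

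Of the 5 tested digestive enzymes of the gut list, 2 rose and 3 fell. The amylase Amy1 rose by 8.03 (SE 0.91) and the maltase-glucoamylase Mgam by 1.70 (SE 0.35), while sucrase-isomaltase, Sis, fell by 3.21 on the log2 scale (SE 0.52). The amylase Amy2a5 fell by 2.50 (SE 0.82; limma adjusted p 0.020), as did Amy2b, outside the list, by 1.39 (SE 0.56; limma adjusted p 0.048). The call of Amy2b was lost with quantile normalization. The sum of the 3 amylases, taken after their values were seen, was 1242 ± 664 in rolling and 1293 ± 106 in stretching (SD, n = 3). Cpb1, a carboxypeptidase, had 1 read in rolling and 69 in stretching, a ratio of 88.6 (95% counting interval 15.4 to 3551). All Amy1 reads of the stretching group lay in stretching 1, and its log2 fold change was 9.17 without that library, while that of Sis was -3.81 without rolling 1. The call of Mgam was lost with scaling to library totals (limma adjusted p 0.057). Among the 3 tested haemocyte and immune genes, Stat5b rose by 2.82 (SE 0.51), Dscam fell by 4.64 on the log2 scale (SE 0.50), and complement C3 had 3 reads against 326 (ratio 140, 47.3 to 680). The fitted log2 fold change of C3 was -5.68, and -5.05 and -6.40 without stretching 1 and 2. The only tested gene of cuticle and chitin, the chitinase Chia1, fell from 117 ± 17.6 to 30.7 ± 17.6.

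Markers of vertebrate tissues, which woodlice lack, had 7 tested members, of which 4 rose and 3 fell. Apart from Csn2, the keratin Krt10 rose from 1.85 ± 2.30 to 247 ± 66.8 (SD, n = 3), and the keratin Krt5 fell from 135 ± 28.7 to 0.878 ± 1.52. The log2 fold change of Krt10 was 6.74, and 6.15 and 7.37 without stretching 1 and 3, and that of Krt5 was -6.44, and -7.07 without rolling 1. The collagen Col3a1 rose by 1.54 (SE 0.44; limma adjusted p 0.010), with an adjusted p of 0.082 with scaling to library totals and 0.066 without rolling 3 and stretching 3. Other milk proteins had few reads. Csn1s1 had 7 reads in rolling and 1 in stretching, Csn1s2b had 0 and 32, Csn3 had 7 and 2, and Wap had none. These milk genes were looked up after the value of Csn2 was seen.

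Genes of protein synthesis moved in both directions. Of 7 tested ribosomal proteins, 4 rose and 3 fell in rolling. Rpl4 was at least 87.7-fold higher in rolling, whereas Rpl3 had 1 read in rolling and 201 in stretching, a ratio of 258 (95% counting interval 45.8 to 10247), and Rps20 fell by 3.05 on the log2 scale (SE 0.49). Of 79 ribosomal proteins in the table, 39 had no read in any library. Among 13 tested translation factors, 4 rose and 7 fell. The elongation factor Eef1a2 had 2 reads in rolling and 2127 in stretching (ratio 1366, 378 to 11287), and the helicase Eif4a1 had 3 and 944 (ratio 404, 138 to 1963). The histone Hist1h3a was at least 455-fold lower in rolling, and H3f3b, another histone H3 gene, had 137 reads in rolling and 1 in stretching (ratio 107, 18.8 to 4243).

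Energy metabolism showed the same mixture. In the list of oxidative phosphorylation and the TCA cycle, 4 of 10 tested genes rose and 3 fell. Fumarase, Fh1, was at least 64.1-fold higher in rolling, the ADP/ATP carrier Slc25a5 had 651 reads against 2 (ratio 253, 69.9 to 2097), and Idh2 fell by 1.32 on the log2 scale (SE 0.36), a call lost with scaling to library totals (limma adjusted p 0.071). Of 7 tested genes of glycolysis and gluconeogenesis, 4 rose and 3 fell. Pck1, which commits carbon to gluconeogenesis, rose from 1.33 ± 1.45 to 492 ± 166 (SD, n = 3). Gapdhs fell by 6.79 on the log2 scale (SE 0.41), and Fbp2 had 1 read in rolling against 741 (ratio 952, 170 to 37642). No gene of the list of mitochondrially encoded genes was in the table.

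Of 29 tested genes of the actin, tubulin and motor list, 11 rose and 8 fell. The alpha-tubulin Tuba3b rose from 66.3 ± 13.9 to 2358 ± 521 and the spectrin Sptan1 from 3.90 ± 1.72 to 132 ± 23.2 (SD, n = 3), and the beta-tubulin Tubb4a fell from 3484 ± 1201 to 327 ± 23.6. Actg1 rose by 1.44 (SE 0.50; limma adjusted p 0.025), but its adjusted p was 0.052 without rolling 2, 0.080, 0.055 and 0.085 without stretching 1, 2 and 3, and 0.120 without rolling 3 and stretching 3. It was 0.101 with scaling to library totals and 0.0575 without a filter. Actb, with 32154 ± 24485 and 58784 ± 8631, was not called (limma adjusted p 0.32, and 0.046 with quantile normalization). Cilia and axoneme genes rose in 3 and fell in 2 of 6 cases. Cfap52 was at least 92.1-fold higher in rolling, and the dynein Dnah5 fell by 4.69 on the log2 scale (SE 0.35) and Tubb4b by 4.93 (SE 0.46).

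**Figure D3:**
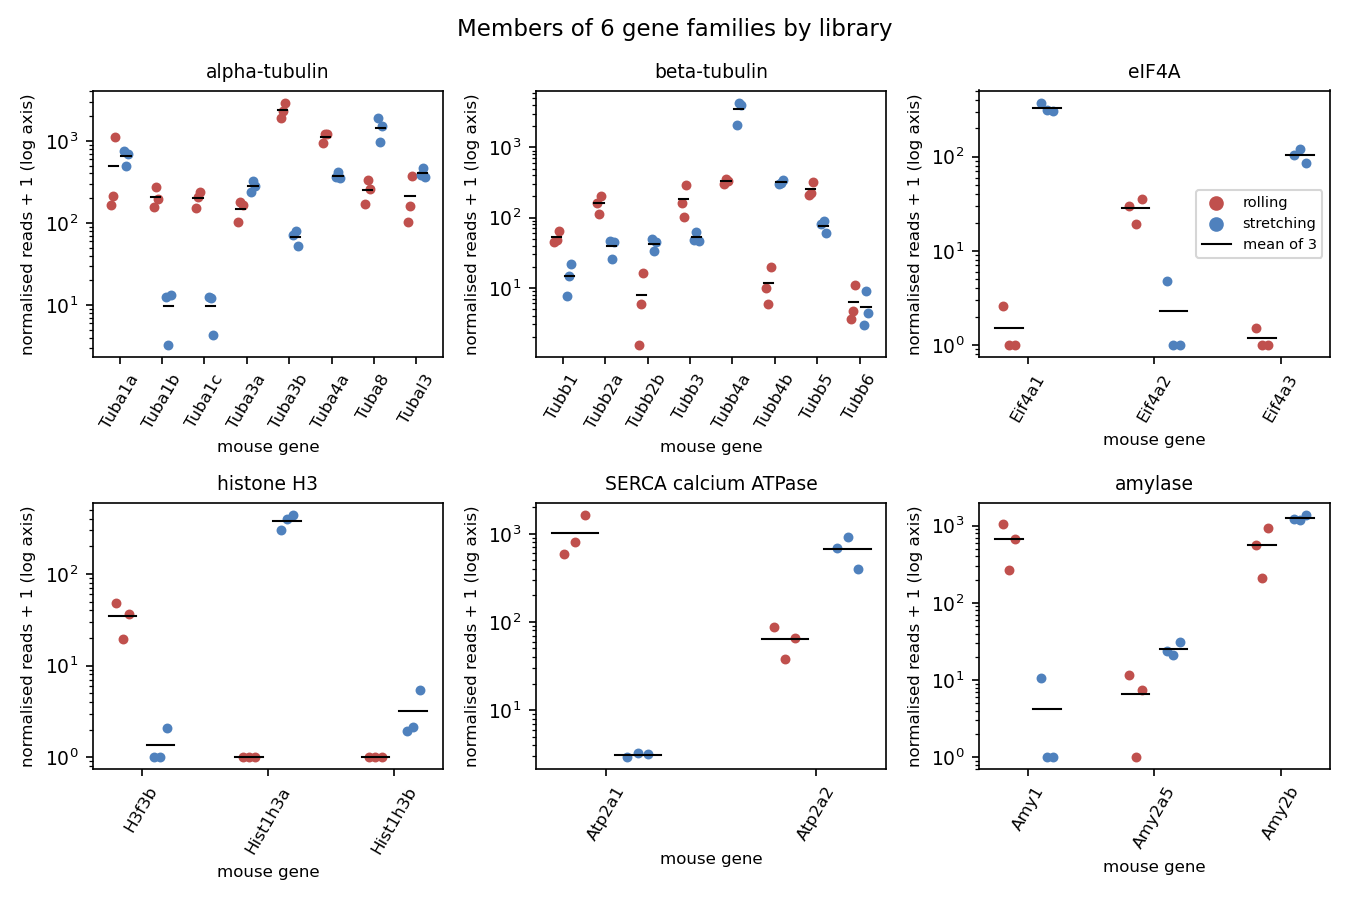
Normalised read count plus 1 (log axis) of mouse genes from 6 families, with 1 point per library and a bar at the mean of 3 in each group. The pairs Atp2a1 and Atp2a2, and H3f3b and Hist1h3a, lie high in opposite groups.

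Chaperones rose in 3 and fell in 4 of 11 tested cases. Hspa1l rose from 7.81 ± 4.57 to 327 ± 7.98, Hspa9 fell from 335 ± 56.7 to 4.20 ± 2.75 and Hsp90aa1 from 194 ± 67.9 to 4.97 ± 1.14 (SD, n = 3). Hspa5, a chaperone of the endoplasmic reticulum, stood at 312 ± 85.9 and 301 ± 28.5 and did not differ by more than the spread between replicates. Of 12 proteasome and ubiquitin genes, 4 rose and 5 fell. Psma4 was at least 24.1-fold higher in rolling, Psmb7 had 278 reads against 1 (ratio 216, 38.5 to 8579), and ubiquitin B, Ubb, had 2 against 507 (ratio 326, 89.7 to 2696). Vcp fell by 3.35 on the log2 scale (SE 1.03; limma adjusted p 0.015), from 86.9 ± 129 to 2.43 ± 0.840. Most of its signal lay in stretching 2, with 8.62, 235 and 16.6 in stretching 1, 2 and 3, and the log2 fold change was -1.95 without that library and -4.26 without stretching 1. Its adjusted p was 0.067 without rolling 1, 0.060 without rolling 2 and 0.060 without rolling 3 and stretching 3.

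Of 8 tested genes of the vacuolar ATPase and ion transport, 5 rose and 1 fell. The proton pump subunits Atp6v1d and Atp6v1a rose by 3.15 (SE 0.63) and 4.24 (SE 0.42), the cotransporter Slc12a1 rose by 3.27 (SE 0.51), and the subunit Atp6v1b2 had 1 read in rolling against 188 (ratio 241, 42.8 to 9588). Without rolling 2 the log2 fold change of Atp6v1d was 2.51, and without stretching 2 that of Atp6v1b2 was -6.20 in place of -5.57. Of 12 splicing and RNA helicase genes, 7 rose and 3 fell. Snrpd1, a core spliceosome protein, was at least 545-fold higher in rolling, and Dhx9 rose by 3.93 (SE 0.60), or by 3.31 without rolling 2, while U2af1 was at least 45.4-fold lower. Of 8 genes of DNA replication and the cell cycle, 1 rose and 4 fell. Mcm6 rose by 2.53 (SE 0.53), Tyms was at least 32.5-fold lower and Pcna had 2 reads against 68 (ratio 43.7, 11.6 to 368). Bub1 fell by 3.19 on the log2 scale (SE 0.93; limma adjusted p 0.012), with log2 fold changes of -2.35 without stretching 1 and -4.40 without stretching 2. Its adjusted p was 0.066 without rolling 1, 0.064 without stretching 1, 0.067 without stretching 3 and 0.091 without rolling 3 and stretching 3.

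Signalling genes of the Wnt, Hedgehog, Notch and TGF-beta pathways rose in 2 and fell in 3 of 9 cases. The receptors Acvr1, with 70 reads against 2 (ratio 27.3, 95% counting interval 7.27 to 229), and Bmpr1a, which fell by 3.82 on the log2 scale (SE 0.39), moved apart, and the Notch ligand Jag1 fell by 1.98 (SE 0.46). The fitted log2 fold change of Acvr1 was 3.47, and 2.72 without rolling 3. Members that were called when adjusted over the list alone were as many as over all genes in each list except that of muscle.

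**Figure D4:**
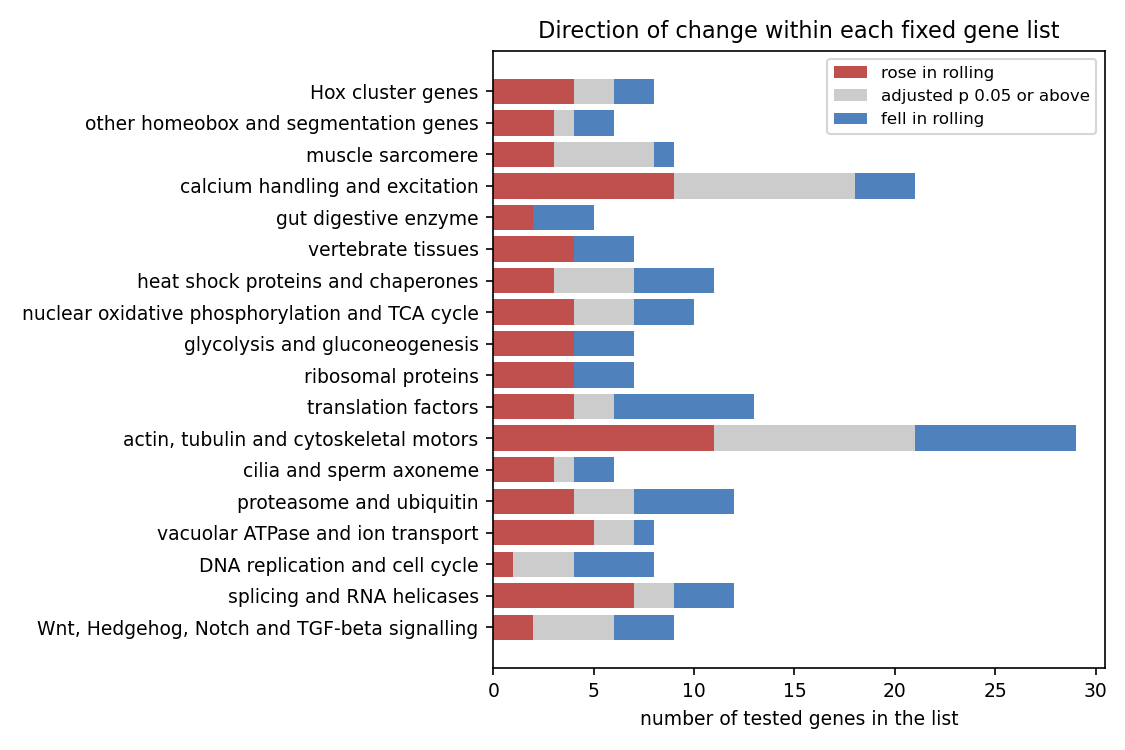
Number of tested genes (x axis) that rose, fell or did not pass the limma threshold in rolling samples in each of the 18 gene lists with at least 5 tested members. Each of the 18 lists held genes that rose and genes that fell.

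None of the 18 lists with at least 5 tested members differed from the other genes by camera of limma, with a lowest Benjamini-Hochberg adjusted p of 0.871, 0 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.893 with an estimated correlation. Fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, called 10 lists, and 18 for change in either direction. The median of the list of oxidative phosphorylation and the TCA cycle was -0.29 and that of the signalling list 0.39, while camera's direction was up and down for these. The mean had camera's direction in each of the 18 lists. Whether camera can find a shifted list where most genes differ was not checked, so its result does not show that no list moved.

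None of the 5 most abundant features was called by limma, and their shares varied widely between libraries. Rn45s, the precursor of ribosomal RNA, took 4.65%, 12.97% and 34.7% of the reads in rolling 1, 2 and 3 and 7.30%, 7.18% and 1.17% in stretching 1, 2 and 3. Its log2 fold change was 1.88 (SE 1.42; limma adjusted p 0.25), with an adjusted p of 0.0074 in the authors' deposited table. The log2 fold change was 0.60 without rolling 3, 1.15 without stretching 3, 3.10 without rolling 1 and -0.13 without both rolling 3 and stretching 3. Lars2 and Mir6236 took 26.0% and 17.6% of the reads in stretching 3 and at most 5.53% and 3.72% in the others. Actin genes took 11.97% to 21.5% of each library, and Lrrc58 stood at 78644 ± 76239 in rolling and 51377 ± 16207 in stretching (SD, n = 3). Without rolling 3 and stretching 3, an alternative chosen after seeing the data, 2006 genes were called.

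The authors' deposited table called 3951 of 10612 features with an adjusted p, 1989 higher and 1962 lower in rolling. Of these, 2050 were among the 2948 genes tested here, and 2035 of them were called in both, all with the same sign. A further 182 genes were called here alone, and 1901 of the authors' calls had a mean under 10.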

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

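The fit without rolling 3 and stretching 3 and the edgeR fit with the authors' size factors were chosen after seeing the data. No gene called by limma was called with the opposite sign under any alternative run. Counts of called genes lay between 1977, with scaling to library totals, and 2256, with a pseudocount of 8, apart from the filters, and between 2076 and 2173 when one sample was left out. Without a filter 5773 genes were called, 2927 higher and 2846 lower, with 14 Hox genes. With a minimum mean of 100, 284 were called, 147 higher and 137 lower, and 0 Hox genes, since none reached that mean. The number of genes tested moved these counts, but the share called also depended on the filter. It was 75.2% in the main test, 31.6% of 18260 genes without a filter and 87.9% of 323 with a minimum mean of 100. Without a filter 2114 of the 2217 calls of the main test were kept. TMM scaling moved the median log2 fold change of all tested genes from 0.10 to -0.02, and library totals moved it to -0.06. Counts within lists moved with the scaling. In the actin, tubulin and motor list 11 rose and 8 fell in the main test, and 8 and 5 with library totals. In the calcium handling list 9 rose and 3 fell in the main test, and 8 and 4 with TMM scaling. The Hox list stayed at 4 and 2 under these scalings. Camera called 0 lists under each alternative run, and fry, which asks another question, called 10.

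The share of variance on principal component 1 was 96.34% with a minimum mean of 100, 90.95% with a pseudocount of 8, and 91.39% to 92.22% when one sample was left out. Of 103 genes followed singly, 97 were called, none of these turned in sign and 86 were called under each alternative in which they were tested. Leaving out one sample moved the fold of 25 of the 97 by over 1.5 times. 3 uncalled values turned. Hspa5 was at -0.11 with TMM scaling, -0.17 with library totals, -0.074 with edgeR and -0.19 to 0.21 when one sample was left out. Hoxa10 ranged from -0.29, without stretching 2, to 1.35, without rolling 2, and Rn45s, at 1.88 in the main test, was at -0.13 without rolling 3 and stretching 3. The cause was not tested.

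No sign of a pairing by replicate number was seen, since deviations of same-numbered samples correlated at 0.02, -0.0066 and 0.0087 across genes. A pairing that leaves no such trace cannot be told, and the labels do not say what the numbers stand for. With the replicate number as a block, 2224 genes were called, 2175 of them also without it. The call of Actg1 was lost with the block (adjusted p 0.05). The number of counted reads limited the test, as 29 of 37 Hox genes with reads and most others were under the level for testing.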

Other observations

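Except for the count of splits of the samples, all tests in this part were chosen after the results they bear on were seen. Groups of genes that had not been listed before were formed by name for a further look. Of 35 tested olfactory receptor genes, 10 rose and 17 fell in rolling by limma with Benjamini-Hochberg adjustment. Of 47 solute carriers, 18 rose and 18 fell, of 68 zinc finger genes of the Zfp series 21 rose and 19 fell, and of 22 collagens 9 rose and 6 fell. Coiled-coil genes of the Ccdc series rose in 17 and fell in 5 of 25 cases and DEAD/DEAH helicases rose in 10 and fell in 1 of 16. None of 16 such groups differed from the other genes by camera, with a lowest adjusted p of 0.178, and 0.698 with an estimated correlation.

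Of 323 genes with a mean of at least 100, 40 were not called, and for 9 of these the log2 fold change and 2 standard errors on either side lay within 2-fold. Among the 9, Calr, the calcium-binding chaperone calreticulin, stood at 117 ± 25.6 in rolling and 119 ± 10.9 in stretching (SD, n = 3), the adhesion gene Dchs1 at 117 ± 13.3 and 112 ± 27.0, and Stt3a, a subunit of the enzyme that adds sugar chains to proteins, at 112 ± 28.1 and 122 ± 19.9. Lars2 and Mir6236 kept a ratio of reads between 1.33 and 1.48 in all 6 libraries, while the share of Lars2 ranged from 1.09% to 26.0%.

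The large number of differing genes, many with reads in one group only, was weighed first. Of the 10 splits of the 6 samples, 1, the real one, gave 2217 calls and the highest of the others 0, but 10 splits are too few for a share under 0.05. Every other split mixes the groups, which puts the difference between them into the spread within each side. Few calls there follow from the separation already reported and add nothing to it. Among 62 tested symbols of essential machinery (ribosome, translation, proteasome, splicing, proton pump and respiration), 41.9% had reads in one group only (26 genes, exact 95% interval 29.5% to 55.2%) against 24.0% of other genes, and their median absolute log2 fold change was 1.39 times that of other genes (95% bootstrap interval 0.999 to 1.62). These values decide neither whether posture switched genes off nor whether sequence differences between the woodlice of the groups may underlie the pattern, since 67 of 250 such symbols had no read in any library and a mouse symbol need not stand for the woodlouse's own gene. RNA of mouse or a close relative as the main source of the counted reads is argued against by a median of at most 1 read per symbol of this kind in any library. A small share of such RNA, or a single transcript, would not be seen in this way. A difference in sequence and a difference in expression between the groups both stay open. They are not the only explanations left, since how mouse names were given to the reads of each group is not stated.

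The second pattern was that members of one family moved apart. In 11 of 12 families described after their values were seen, members rose and fell in the main test. This count moved with the scaling. With library totals 0 sodium-potassium ATPase genes rose and 1 fell, and with quantile normalization 2 actins rose and 1 fell. The alpha-tubulins, for example, ranged from -2.50 to 5.13 on the log2 scale while their sum changed by 0.60 (SE 0.26; exact permutation p 0.2). Reads of one woodlouse family split between near-identical mouse copies could make members move apart. Sums were compared over 385 families formed by symbol root, which groups genes by name and not by likeness of sequence. H3f3b and Hist1h3a, for example, have different roots, and Hox genes are grouped by cluster. The sums therefore bear on such splitting only indirectly. Their median absolute log2 fold change was 1.38, against 1.54 in random sets of like mean, with a share of 0.041 of 1000 draws as low. That share is close to 0.05, and it comes from the second version of the test, since a first version on the 12 families (median 0.485, share 0.0060) was set aside because they had been picked knowing that their members moved apart. The effect is small. Sums of beta-tubulin, eIF4A and histone H3 genes still differed by -1.99, -3.95 and -3.52, and that of Hox group 9 by 1.36 (exact permutation p 0.1 each, the smallest possible). The sums of the other described families changed by -0.37 to 0.65 (exact permutation p 0.2 or above). Splitting within a family would leave its sum unchanged only if each read was counted on a listed member. How reads were counted is not given, so these sums do not decide the question.

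The third pattern was the change in Hox genes. Hox genes were called in 75.0% of tested cases and all genes in 75.2%. No larger change was seen in the tested Hox genes than in others. Their median absolute log2 fold change of 2.84 lay at percentile 56.2 of 10000 random lists of like mean, which had a median of 2.67. A small difference could not be seen with so few genes, since the random lists spread from 1.15 to 4.15 (5th to 95th percentile). Splitting of reads between Hox paralogues may contribute, but the sum of all Hox genes changed by 1.11 (SE 0.11), and by 0.98 with TMM scaling and 0.92 with library totals, an interval that spans the 2-fold limit set for the test and leaves it open. A regulation of Hox genes with posture stays among the open explanations, untested by this design.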
